A study of Mus musculus with 6 samples.

How the data were processed

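RNA-seq had been carried out on 6 samples of mesonephroi of male mouse embryos at embryonic day 16.5. Per the labels' protocols, tissue was frozen quickly, RNA was isolated with the PicoPure kit, polyadenylated RNA was captured with poly-T beads, and cDNA was made from fragmented RNA with random hexamers. Whether the kit marked strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart. The labels put 3 samples in a control group (Osr2-Cre with 1 floxed and 1 unfloxed Gata2 allele) and 3 in a Gata2cKO group (Osr2-Cre with both alleles floxed).

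The data came as a single gene table of 14366 genes with 1 value per gene and library. The deposited values of each library summed to between 997351 and 998844, low values showed no whole-read steps, and short ribosomal protein genes were among the highest, so the unit was taken to be TPM (transcript abundance scaled for gene length and library total) made by the authors, from the values and not from a header. STAR 2.7.11a, DESeq2, DESeq and the GRCm38 build are named per the submitters' processing notes, with no roles given. The quantifier and the rule by which genes were kept in the table are not given in the sources used here. The gene annotation is given only as a tag, M10, beside the build in the name of the table, which was not checked against a release. The same table holds the authors' log2 fold change of Gata2cKO over control for each gene. It also holds the authors' p-value and an adjusted p that equals the Benjamini-Hochberg adjustment over the 14366 listed genes to within 1.8e-15. The authors' log2 fold changes lay below the log2 ratio of the mean TPM values by a nearly constant amount (median difference -0.06, SD 0.0064 across tested genes). TPM keeps no read depth, so the depth of each library is unknown, and no counting interval is given. Replicate spread is the measure of error.

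Each column was assigned to its sample through the library name in the labels. Gene positions are those of GENCODE release 21 for mouse (GRCm38), matched by gene identifier without its version for 14351 of the 14366 genes. Of the matched genes, 99.6% were protein-coding.

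The design fixed before the data were examined called for a count test where counts were given and for limma-trend on log2 values where only normalized values were. The second applied. Genes with a TPM of 1 or more in at least 3 of the 6 libraries were kept, which left 12300 genes. A linear model with 1 term for the group was fitted to log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean (limma-trend), and p-values were adjusted over the 12300 genes by the Benjamini-Hochberg method with a threshold of 0.05. All adjusted p-values for genes in the results are from this limma test unless the authors' deposited table is named. All tests were two-sided unless stated. Log2 fold changes are Gata2cKO minus control on the log2(TPM + 1) scale, which understates the change of genes with low values. Fold values are ratios of mean TPM.

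A set of 33 gene lists, fixed before the data were examined, covered the mesenchyme and epithelium of the duct, signalling pathways, cell state, and markers of other cell types that the dissected tissue could hold. The 30 lists with at least 5 tested members were tested against all other genes with camera, with a preset correlation between genes of 0.01, and adjusted over the 30 lists. Camera with an estimated correlation was an alternative. The rotation test fry, also run, asks a different question, whether the members of a list changed at all and not whether they changed more than other genes. The lists of skeletal muscle markers and of sex chromosome genes had 4 tested members each and the list of adrenal and chromaffin markers had 0, so these were not tested as lists.

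Genes named in the text follow a rule fixed before the data were examined. It takes Gata2, the 8 highest and 8 lowest log2 fold changes among genes past the threshold with a mean TPM of 1 or more and all 3 Gata2cKO libraries on the same side of all 3 controls, and the 8 genes with the smallest adjusted p. It adds up to 4 members of each list with the smallest adjusted p past the threshold, up to 2 in the less common direction, or the member with the smallest p where none passed. The most abundant member is added for lists of other cell types. Predicted genes without a standard symbol were left out, and a few genes that the rule takes are not reported here, although they count in the totals of changed genes and of lists. Any other gene named was chosen after its values were seen, and the text says so where it appears.

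The model was tested on simulated data made from the means and residual spreads of the 12300 genes with 200 genes changed. For the comparison of Gata2cKO with control it recovered 34.3% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 100% of those changed 4-fold. Of the 12100 unchanged genes 9 were called. These shares hold for the simulated changed genes and give no recovery rate for tested genes with low values. The simulation took only means and residual spreads, so variation shared by many genes of a library was not part of it. Both the recovery and the count of false calls may therefore be too favourable.

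Alternatives were other pseudocounts (0.1 and 5), no filter on low values, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were 2 other scalings of the TPM, a total without mitochondrial genes, a higher TPM filter, a weight per library, removal of each library's GC trend (lowess with a span of 0.3 over the exonic GC content of 12284 genes), and the authors' deposited test. Figures were drawn with matplotlib 3.10.9.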

Results

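The transcriptome of the mesonephros was measured in 6 samples from male mouse embryos at embryonic day 16.5. This embryonic tissue holds the Wolffian duct and its surrounding mesenchyme and gives rise to the epididymis in males. The dissected tissue included the region of the mesonephric tubules. There were 3 control samples and 3 samples labelled Gata2cKO, in which the transcription factor gene Gata2 was to be removed from cells that express Osr2-Cre, a recombinase driven in mesenchyme. Controls also carried the recombinase, with 1 floxed allele. The comparison asks what mesenchymal Gata2 does in the development of the Wolffian duct and epididymis. The labels do not state whether samples of a group came from separate embryos or litters, so p-values measure the spread between these samples. Read depth is unknown because values were given as TPM.

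The 6 libraries listed between 12122 and 12301 genes at a TPM of 1 or more. Correlations of log2(TPM + 1) across tested genes ranged from 0.985 to 0.996 within controls, from 0.994 to 0.995 within Gata2cKO and from 0.978 to 0.989 between the groups, where genes are not independent replicates. The first principal component, with 49.3% of the variance, separated the groups. The second, with 27.4%, set control replicate 1 (20.1) apart from control replicates 2 and 3 (-12.7 and -17.1). Mitochondrially encoded transcripts made up 21.9% of the TPM in control replicate 1, 16.3% and 14.2% in control replicates 2 and 3, and 15.2%, 13.2% and 13.7% in Gata2cKO replicates 1, 2 and 3. Summed histone transcripts reached 2768 TPM in control replicate 1, 1459 and 1439 TPM in the other controls, and 1129, 1134 and 1394 TPM in Gata2cKO replicates 1 to 3. Summed adult and embryonic globin transcripts were 18277 TPM in control replicate 1, 6868 and 7818 TPM in the other controls and 12071, 13821 and 10520 TPM in the Gata2cKO libraries.

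**Figure D1:**
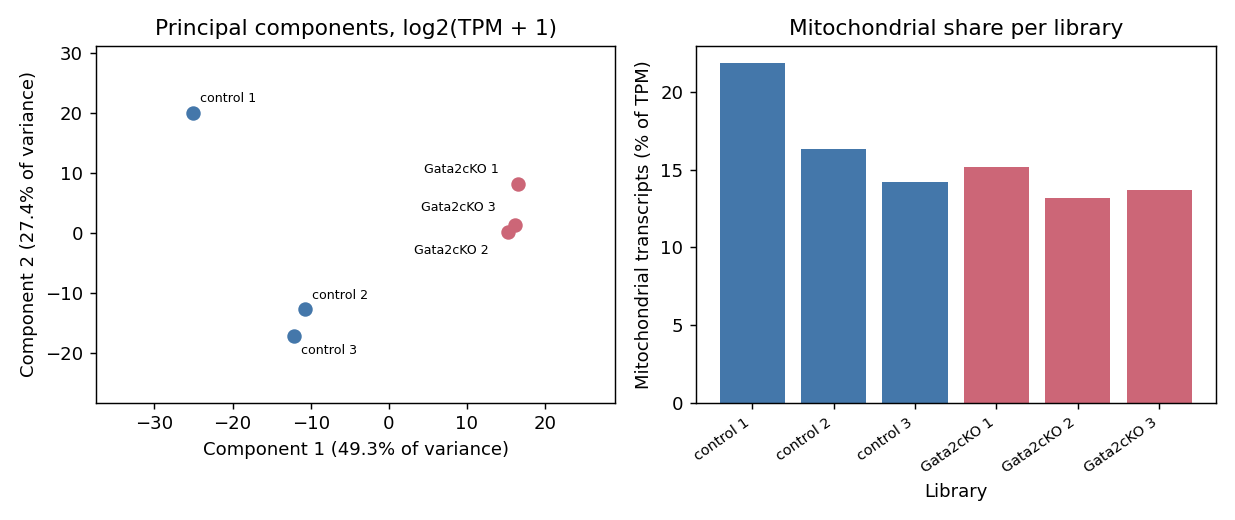
Left, the 6 libraries on principal components 1 and 2 of log2(TPM + 1), with controls in blue and Gata2cKO in red; right, bars from 0 with the percent of each library's TPM from mitochondrially encoded genes. Control replicate 1 lies at 20.1 on component 2 and has the highest mitochondrial share (21.9%).

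Gata2 itself did not differ at the level of the whole gene. Its level was 384, 464 and 546 TPM in control replicates 1, 2 and 3 and 431, 530 and 416 TPM in Gata2cKO replicates 1, 2 and 3, with means of 465 ± 81.2 and 459 ± 61.9 TPM (SD, n = 3 each). The log2 fold change was -0.01 (SE 0.15, limma adjusted p = 0.968), and the authors' deposited table gives -0.08 (adjusted p = 0.740). Gata2 lies on chromosome 6 from 88193891 to 88207032 (GRCm38). A gene-level TPM sums reads over all exons and does not show whether the floxed part was lost, and cells without the recombinase also contribute. This value therefore does not check the labels, and each direction given here rests on them. Osr2, whose promoter drives the recombinase, fell from 261 ± 54.1 to 127 ± 9.35 TPM (SD, n = 3 each; log2 fold change -1.02, SE 0.15, limma adjusted p = 0.0136). That call was lost without Gata2cKO replicate 1 (adjusted p = 0.0605) and in 1 other of the 6 removals of a library. Gata5 was the member of the Gata family list past the threshold, at 13.9 ± 0.224 TPM in controls and 9.58 ± 0.732 TPM in libraries labelled Gata2cKO (SD, n = 3 each). It fell by 0.50 on the log2 scale (limma adjusted p = 0.0184, 0.0823 without Gata2cKO replicate 1). The other 5 of the 6 tested members, Gata2 included, did not pass, and adjusted over the list alone 1 rose and 1 fell.

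Foxl2 fell and Foxl1 rose by over 10-fold in libraries labelled Gata2cKO, and genes of other transcription factors, secreted proteins and a receptor changed as well. Foxl2, a forkhead transcription factor (chromosome 9, 98955288 to 98958543), fell 10.6-fold from 122 ± 22.6 to 11.6 ± 2.93 TPM (SD, n = 3 each; log2 fold change -3.30, SE 0.18, limma adjusted p = 0.00165). Foxl1, a forkhead factor known from gut mesenchyme (chromosome 8, 121127940 to 121130644), rose 12.9-fold from 2.02 ± 0.858 to 26.2 ± 6.07 TPM (log2 fold change 3.18, SE 0.22, limma adjusted p = 0.00173). Shox2, a homeobox transcription factor, rose from 0.310 ± 0.172 to 3.21 ± 0.264 TPM, a level near the floor in controls. Dkk1, a secreted Wnt antagonist, rose 4.11-fold from 3.14 ± 0.495 to 12.9 ± 0.919 TPM. Nov, a matricellular protein gene, rose 6.10-fold from 1.60 ± 0.806 to 9.74 ± 0.906 TPM. Adh1, an alcohol dehydrogenase that also oxidizes retinol, rose 2.86-fold from 8.45 ± 0.908 to 24.1 ± 2.12 TPM. Htatsf1 on the X chromosome, which encodes a factor in transcription elongation and splicing, fell 2.26-fold from 214 ± 5.92 to 95.0 ± 3.49 TPM. Insrr, an orphan receptor of the insulin receptor family, fell from 4.99 ± 0.0982 to 1.19 ± 0.289 TPM. Adra2c, an adrenergic receptor gene, rose from 2.86 ± 1.51 to 13.6 ± 1.35 TPM, and Fxyd4, a regulator of the sodium pump, from 0.874 ± 0.354 to 5.48 ± 0.506 TPM. These genes stayed past the threshold in each of the 6 removals of a library.

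**Figure D2:**
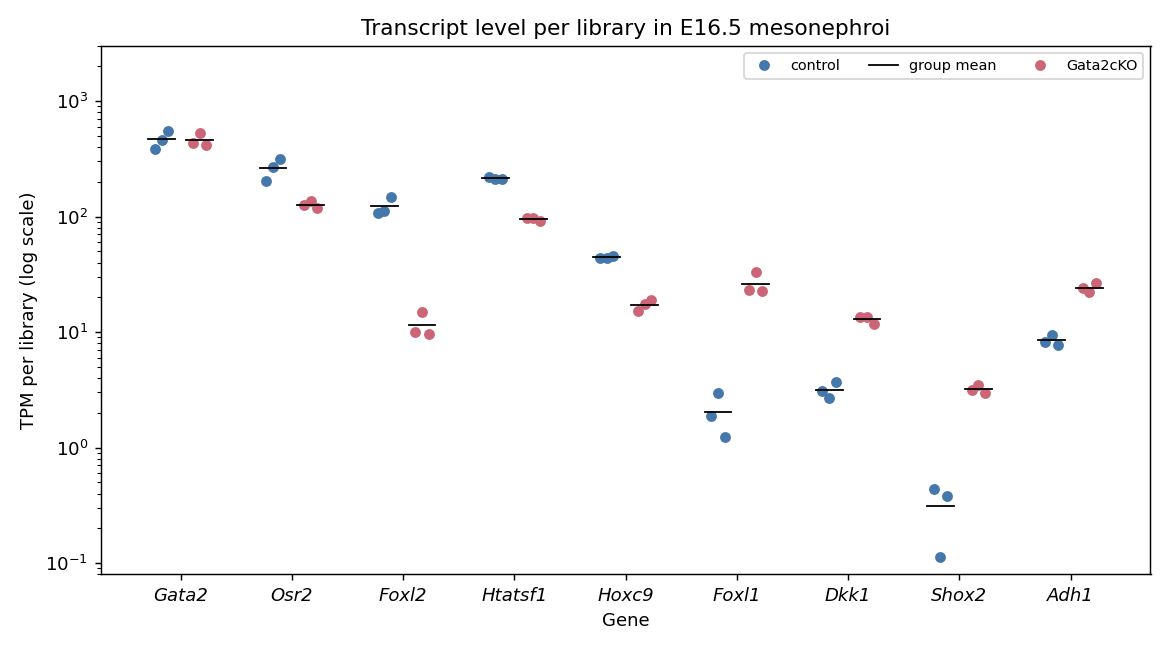
TPM on a log axis of 9 named genes in each library, with controls in blue, Gata2cKO in red and the mean of each group of 3 as a black line. Gata2 overlaps between the groups, whereas Foxl2 falls from 107, 112 and 148 TPM in controls to 10.1, 15.0 and 9.71 TPM, and Foxl1 rises from 1.88, 2.94 and 1.25 TPM to 22.9, 33.2 and 22.5 TPM.

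In all, 919 of 12300 tested genes (7.47%) passed the threshold, 705 higher and 214 lower in libraries labelled Gata2cKO (76.7% higher). With a median-of-ratios scaling of the TPM, which sets the median log2 fold change of all genes from 0.05 to near 0, the split was 502 higher and 397 lower (55.8% higher). It was 578 and 342 with upper-quartile scaling (62.8% higher) and 432 and 282 without mitochondrial genes in the total (60.5% higher). Of the 919 genes, 76 had a log2 fold change of at least 1 in size. In all 919 the 3 Gata2cKO values lay on the same side of the 3 control values, which selection by p nearly ensures. That arrangement was found for 33.9% of all tested genes where chance gives 10% on average. Genes vary together, so the share can lie far from 10% by chance and is no test of the groups. The count was 1539 without control replicate 1, 259 without control replicate 2 and 274 without control replicate 3. It was 116 without Gata2cKO replicate 1, 230 without Gata2cKO replicate 2 and 206 without Gata2cKO replicate 3. The authors' deposited table gives 1906 genes at an adjusted p under 0.05, 961 higher and 945 lower, and 811 of the 919 genes are among them, all in the same direction. Of 90 named genes past the threshold, 32 kept their call in each of the 6 removals.

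Hox genes, the homeobox genes that give cells their position along the body axis, were lower as a group in camera at its preset correlation. The shift was not uniform, with a negative log2 fold change for 17 tested members and a positive one for 6. Those 6 lay in the HoxB and HoxD clusters, which also held members that were lower, a split seen after the values. Of the 23 tested members 8 fell and 1 rose (adjusted over the list alone, 9 fell and 2 rose), and camera placed the list below other genes (adjusted p = 0.000151; adjusted p = 0.593 with an estimated correlation). Hoxc9 fell 2.58-fold from 44.4 ± 1.24 to 17.2 ± 1.81 TPM (SD, n = 3 each; log2 fold change -1.32, SE 0.09, limma adjusted p = 0.00173). Hoxc8 fell from 364 ± 41.1 to 159 ± 34.5 TPM, Hoxc6 from 64.8 ± 1.92 to 36.5 ± 3.50 TPM and Hoxa9 from 162 ± 14.0 to 95.7 ± 1.58 TPM. These 4 kept their calls in each of the 6 removals. Hoxd8 went the other way, from 235 ± 15.3 to 331 ± 14.0 TPM (log2 fold change 0.50, limma adjusted p = 0.0182), and lost its call in 5 of the removals (highest adjusted p 0.0903, without Gata2cKO replicate 1). Without control replicate 1 the list had 8 members that fell and 1 that rose, with a median log2 fold change of -0.16 against -0.30 in all libraries. In the other removals 5 to 7 fell and 0 rose.

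Genes of the mesenchyme moved both ways. In the list of mesenchymal genes 5 of 20 tested members fell and 3 rose (5 and 5 adjusted over the list alone). When 1 library was left out 1 to 5 fell and 0 to 3 rose, fewest without Gata2cKO replicate 1 (1 and 0). Tcf21, a basic helix-loop-helix factor of urogenital mesenchyme, fell from 766 ± 63.2 to 449 ± 15.2 TPM (SD, n = 3 each; log2 fold change -0.76, SE 0.09, limma adjusted p = 0.00856). Nr2f1, an orphan nuclear receptor, fell from 204 ± 34.0 to 103 ± 15.1 TPM, and Osr2 is given above. Nr2f2 and Twist2, named after their values were seen, were the other members that fell. Lox, which crosslinks collagen and elastin, rose from 146 ± 24.3 to 255 ± 12.4 TPM. Mfap5, a microfibril gene, rose from 1.02 ± 0.135 to 2.22 ± 0.383 TPM, and Foxf1, named after its values were seen, was the third. Tcf21 kept its call in each removal of a library. Nr2f1, Lox and Mfap5 lost theirs in 3 removals each (highest adjusted p 0.0657 without Gata2cKO replicate 1, 0.0588 without Gata2cKO replicate 3 and 0.0877 without Gata2cKO replicate 1). The list as a whole was not shifted (camera adjusted p = 0.676, with a median log2 fold change of 0.11, a mean of 0.03 and a downward direction in the test).

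Smooth muscle genes were lower as a group in camera at its preset correlation. Of 16 tested members 3 fell and 0 rose (3 fell and 1 rose adjusted over the list alone): the smooth muscle myosin gene Myh11 from 4.49 ± 0.783 to 1.85 ± 0.214 TPM, the actin gene Acta2 from 315 ± 50.6 to 196 ± 11.9 TPM and the myosin light chain gene Myl9 from 355 ± 34.5 to 257 ± 14.2 TPM (SD, n = 3 each). Their limma adjusted p-values were 0.0114, 0.0230 and 0.0330. Myh11 kept its call in each removal of a library, whereas Acta2 and Myl9 lost theirs without Gata2cKO replicate 3 (adjusted p = 0.0974 and 0.124) and in others. Over the 6 removals 1 to 4 fell and at most 1 rose. The list lay below other genes by camera (adjusted p = 0.0135; adjusted p = 0.593 with an estimated correlation).

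Extracellular matrix genes were higher as a group in camera at its preset correlation. Of 35 tested members 12 rose and 2 fell (15 and 2 adjusted over the list alone), and the list lay above other genes (camera adjusted p = 0.00103; adjusted p = 0.593 with an estimated correlation). Postn, a matricellular protein gene, rose 2.25-fold from 168 ± 21.4 to 377 ± 22.4 TPM (SD, n = 3 each; log2 fold change 1.17, SE 0.11, limma adjusted p = 0.00440). The collagen genes Col15a1 and Col5a2 rose from 11.7 ± 1.13 to 26.4 ± 2.91 TPM and from 48.0 ± 3.57 to 83.1 ± 3.67 TPM, and the fibrillin gene Fbn1 rose from 7.98 ± 0.671 to 14.2 ± 0.781 TPM. These 4 kept their calls in each removal of a library. The 2 that fell were the proteoglycan gene Vcan, from 86.2 ± 11.6 to 52.9 ± 7.11 TPM, and the matrix protein gene Spon1, from 1.59 ± 0.138 to 0.835 ± 0.164 TPM. Both lost their calls in 5 of the 6 removals (highest adjusted p 0.0879 without Gata2cKO replicate 3 and 0.107 without Gata2cKO replicate 1). There were 14 that rose and 2 that fell without control replicate 1, in the other removals 4 or 5 and 0, and with median-of-ratios scaling 9 and 2.

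Epithelial and mesothelial markers, and a few of the markers of renal tubules and glomeruli, were higher as well in camera at its preset correlation. Among markers of the Wolffian duct epithelium 6 of 23 tested members rose and 0 fell (8 and 0 adjusted over the list alone), with camera adjusted p = 0.00135 (adjusted p = 0.593 with an estimated correlation). The count was 11 that rose without control replicate 1, and in the other removals 0 to 3 rose and at most 1 fell. The tight junction gene Cldn4 rose from 160.5 ± 6.40 to 243 ± 13.4 TPM and the adhesion gene Epcam from 74.1 ± 5.20 to 102 ± 4.40 TPM (SD, n = 3 each; limma adjusted p = 0.0113 and 0.0233). These lost their calls without Gata2cKO replicate 1 (adjusted p = 0.0556 and 0.0896). The list of markers of renal tubules and glomeruli was written with 19 genes, of which 8 were in the deposited data and 6 were tested. Of these 6 tested members 4 rose (4 adjusted over the list alone, and 2 to 4 over the removals). Camera gave this list an adjusted p of 0.00579 (adjusted p = 0.593 with an estimated correlation). The members that rose were few of the markers written. These 4 were the sialomucin gene Podxl, the most abundant, from 53.3 ± 3.85 to 89.6 ± 4.60 TPM, the transcriptional coregulator gene Cited1 from 7.68 ± 1.10 to 17.4 ± 2.72 TPM, the water channel gene Aqp1 from 18.6 ± 0.494 to 29.2 ± 2.57 TPM and the endocytic receptor gene Lrp2 from 1.47 ± 0.208 to 2.64 ± 0.0674 TPM. Podxl and Cited1 kept their calls in each removal, while Aqp1 and Lrp2 did not (highest adjusted p 0.0532 without Gata2cKO replicate 3 and 0.0798 without Gata2cKO replicate 1). Of the mesothelial markers 4 of 10 rose (7 adjusted over the list alone; 1 to 4 over the removals; camera adjusted p = 0.00103; adjusted p = 0.593 with an estimated correlation). Among them Lrrn4 rose from 21.04 ± 1.27 to 44.0 ± 3.69 TPM and the most abundant, the uroplakin gene Upk3b, from 165 ± 24.9 to 279 ± 20.8 TPM. Lrrn4 kept its call in each removal and Upk3b lost it without Gata2cKO replicate 3 (adjusted p = 0.0700) and in 2 others. All tested members of these lists had a mean of 1 TPM or more in controls, and Krt19 is in both the epithelial and the mesothelial list.

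**Figure D3:**
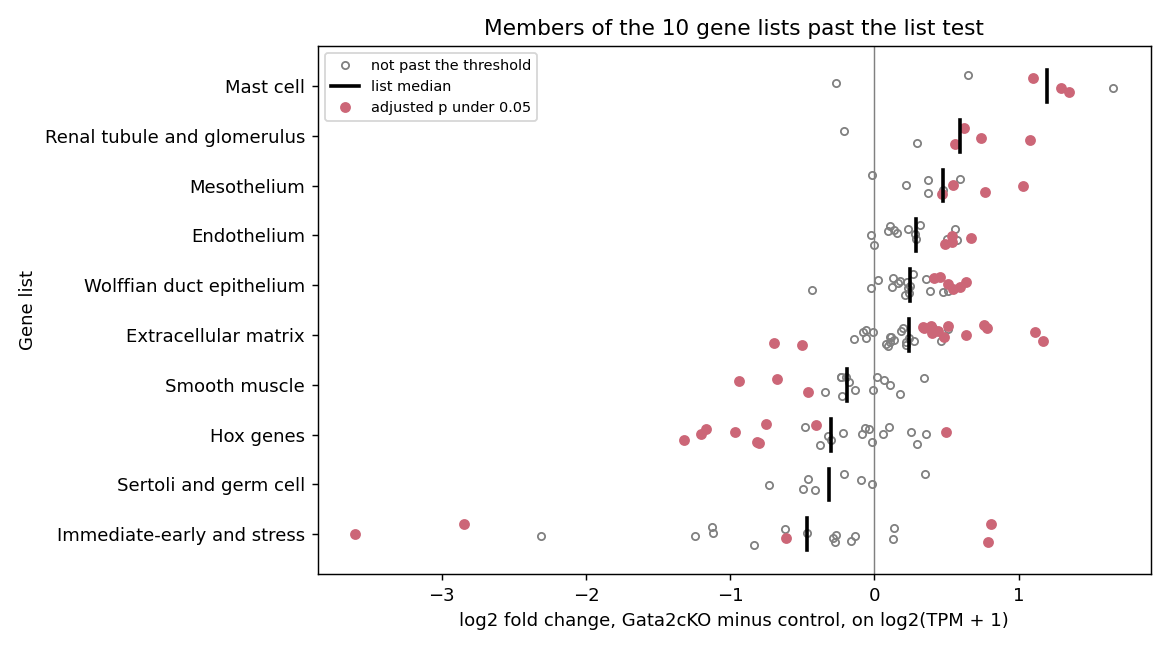
Log2 fold change on log2(TPM + 1), Gata2cKO minus control, of each tested member of the 10 lists past the camera test, with genes past the threshold filled in red, others as open circles and the list median as a black line. Mast cell markers have the highest median (1.197) and immediate-early and stress genes the lowest (-0.47).

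Markers of mast cells, which are granule-bearing immune cells, had the highest median log2 fold change of the 30 tested lists (1.197). Of 6 tested members 3 rose (5 rose and 1 fell adjusted over the list alone): the protease genes Tpsb2, the most abundant, from 68.8 ± 9.45 to 169 ± 5.10 TPM, Cma1 from 31.8 ± 6.32 to 81.6 ± 5.27 TPM and Cpa3 from 4.003 ± 1.04 to 9.63 ± 1.09 TPM (SD, n = 3 each; log2 fold changes 1.29, 1.35 and 1.10, limma adjusted p = 0.00261, 0.00618 and 0.0122). Tpsb2 belongs to a family of similar proteases and its value is uncertain to that extent. Camera gave an adjusted p of 0.00374 (adjusted p = 0.593 with an estimated correlation). Tpsb2 and Cma1 kept their calls in each removal of a library, and Cpa3 lost its call without Gata2cKO replicate 1 (adjusted p = 0.0556) and in 1 other. Prss34, a serine protease gene of mast cells and basophils that is not in the list, rose 3.65-fold from 5.01 ± 1.61 to 18.3 ± 3.09 TPM (limma adjusted p = 0.0101). S100a8 and S100a9, which encode the calprotectin subunits of neutrophils, rose from 12.1 ± 6.12 to 58.0 ± 34.7 TPM and from 4.19 ± 3.52 to 22.5 ± 15.3 TPM (limma adjusted p = 0.0330 and 0.0481), with the highest values in Gata2cKO replicate 1. Both lost their calls in 5 of the 6 removals (highest adjusted p 0.0907 without Gata2cKO replicate 3 and 0.130 without Gata2cKO replicate 1).

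Endothelial markers were also higher as a group in camera at its preset correlation. Of 17 tested members 4 rose and 0 fell (7 and 0 adjusted over the list alone), with camera adjusted p = 0.00103 (adjusted p = 0.593 with an estimated correlation). Removals of a library gave 0 to 5 that rose, 0 without Gata2cKO replicate 1. Esam, an endothelial adhesion molecule gene, rose from 30.3 ± 0.973 to 44.3 ± 0.478 TPM and Pecam1 from 5.77 ± 0.796 to 8.78 ± 0.615 TPM (SD, n = 3 each; limma adjusted p = 0.0112 and 0.0328; adjusted p = 0.0556 and 0.126 without Gata2cKO replicate 1). The most abundant member, Sox18, was at 165 ± 21.8 and 205 ± 15.1 TPM and did not pass (adjusted p = 0.132). Of the macrophage markers 2 of 15 rose (4 adjusted over the list alone), the lysozyme gene Lyz2 from 38.6 ± 6.91 to 74.9 ± 5.40 TPM and the mannose receptor gene Mrc1 from 4.25 ± 0.450 to 6.15 ± 0.470 TPM (limma adjusted p = 0.0127 and 0.0393; adjusted p = 0.0549 without Gata2cKO replicate 3 and 0.144 without Gata2cKO replicate 1). C1qa, the most abundant, did not pass (120 ± 15.6 and 144 ± 9.54 TPM). Neural and Schwann cell markers had 2 of 9 that rose, S100b and Fabp7 (4 rose and 1 fell adjusted over the list alone). Both lost their calls without Gata2cKO replicate 3 (adjusted p = 0.0676 and 0.141). The macrophage and neural lists did not pass camera (adjusted p = 0.160 and 0.114), but both passed without control replicate 2 (adjusted p = 0.0232 each), and the neural list also without Gata2cKO replicate 1 (adjusted p = 0.0313). Among erythroid genes 1 of 9 rose, the anion exchanger gene Slc4a1 from 1.04 ± 0.450 to 2.18 ± 0.145 TPM (camera adjusted p = 0.605; 1 adjusted over the list alone), and it lost its call in 5 removals (highest adjusted p 0.135 without Gata2cKO replicate 1). Without control replicate 1, the library with the highest globin level, 5 rose and the list passed (adjusted p = 0.0157), and in the other removals 0 rose and it did not pass. Hba-a1, the most abundant, was at 6096 ± 3230 and 6009 ± 970 TPM, and its reads can be shared with a near-identical copy.

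In the Wnt list 9 of 41 tested members rose and 1 fell (13 and 2 adjusted over the list alone), but the list did not pass as a whole (camera adjusted p = 0.142). The removal of control replicate 1 gave 10 and 3, and each other removal 3 or 4 and 0. Besides Dkk1, the ligand gene Wnt7b rose 2.45-fold from 2.11 ± 0.319 to 5.17 ± 0.109 TPM, the receptor gene Fzd4 from 53.5 ± 3.95 to 86.8 ± 2.16 TPM and the secreted inhibitor gene Wif1 from 0.480 ± 0.172 to 1.82 ± 0.469 TPM (SD, n = 3 each; limma adjusted p = 0.00549, 0.00884 and 0.0178). Wnt5a, a ligand of non-canonical signalling, fell from 261 ± 24.9 to 181 ± 15.7 TPM (limma adjusted p = 0.0284). Dkk1, Wnt7b and Fzd4 kept their calls in each removal of a library, and Wif1 and Wnt5a lost theirs without Gata2cKO replicate 3 (adjusted p = 0.0713 and 0.105) and in others.

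Nog and Chrd, antagonists of bone morphogenetic protein (BMP) signalling, fell together with the ligand gene Bmp2. In the list of TGF-beta and BMP genes 4 of 36 tested members rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.945). With median-of-ratios scaling 2 rose and 4 fell, and with 1 library left out 0 to 3 rose and 1 to 5 fell. The 3 that fell were Nog, from 85.5 ± 12.2 to 38.2 ± 6.57 TPM, Chrd, from 76.1 ± 3.72 to 49.0 ± 6.76 TPM, and Bmp2, from 20.7 ± 3.84 to 10.5 ± 1.16 TPM (SD, n = 3 each; limma adjusted p = 0.0107, 0.0189 and 0.0175). Id2, a transcriptional target of the pathway, rose from 416 ± 2.17 to 608 ± 33.8 TPM (limma adjusted p = 0.0128), and Gdf10, Tgfbr2 and Smad2, named after their values were seen, also rose. Nog kept its call in each removal of a library, whereas Chrd, Bmp2 and Id2 lost theirs without Gata2cKO replicate 1 (adjusted p = 0.0877, 0.0714 and 0.0704) and in others.

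In the hedgehog list 1 of 15 tested members rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.184). Gli1, a transcriptional target of the pathway, fell from 238 ± 26.7 to 153 ± 24.99 TPM and the coreceptor gene Cdon rose from 26.4 ± 1.02 to 38.5 ± 0.716 TPM (SD, n = 3 each; limma adjusted p = 0.0350 and 0.0119; adjusted p = 0.124 and 0.0640 without Gata2cKO replicate 1). In the list of FGF and RET signalling 3 of 20 rose (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.673), the growth factor genes Fgf1 and Fgf18 and the receptor gene Met, with Fgf1 from 2.13 ± 0.243 to 4.12 ± 0.397 TPM. Fgf1 lost its call in 1 of the 6 removals, Met in 5 and Fgf18 in all 6 (highest adjusted p 0.0520, 0.0903 and 0.133). In the insulin-like growth factor list 3 of 12 rose (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.480). They were Igf1, from 22.9 ± 0.418 to 39.7 ± 0.750 TPM (log2 fold change 0.77, SE 0.07, limma adjusted p = 0.00375), which kept its call in each removal, and the binding protein genes Igfbp2 and Igfbp5, which did not (adjusted p = 0.124 and 0.186 without Gata2cKO replicate 1). In the retinoic acid list 2 of 16 rose (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.453), Aldh1a3, which makes retinoic acid, from 7.37 ± 1.38 to 12.98 ± 0.748 TPM, and Rdh10, which makes its precursor, from 31.9 ± 1.55 to 40.7 ± 1.92 TPM. Both lost their calls in 5 of the 6 removals (highest adjusted p 0.0728 without Gata2cKO replicate 3 and 0.172 without Gata2cKO replicate 1). In the Notch list 1 of 14 rose, the glycosyltransferase gene Lfng (limma adjusted p = 0.0360, 0.118 without Gata2cKO replicate 1; 2 adjusted over the list alone; camera adjusted p = 0.299).

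Androgens drive the growth of the Wolffian duct, and of the list of androgen-responsive genes 4 of 17 tested members rose and 0 fell, also adjusted over the list alone. Among them were Igf1, Ndrg1 (5.69 ± 0.174 to 9.71 ± 0.584 TPM) and Ncoa4 (28.5 ± 2.14 to 40.9 ± 0.450 TPM; SD, n = 3 each), with limma adjusted p-values of 0.00375, 0.00971 and 0.0170. Over the removals of a library 2 to 4 rose and at most 1 fell. Igf1 and Ndrg1 kept their calls in each, and Ncoa4 lost its call in 4 removals (highest adjusted p 0.0777, without Gata2cKO replicate 1). The list did not pass camera (adjusted p = 0.142). Directional fry, which does not set a list against other genes, called it (adjusted p = 0.0174). Of 6 tested genes of steroid hormone synthesis 0 passed limma in either direction, also adjusted over the list alone, 1 had an unadjusted p under 0.05 and the authors' deposited table calls 0 (camera adjusted p = 0.605). Scarb1 had the smallest p (5.99 ± 0.155 and 7.66 ± 0.895 TPM, limma adjusted p = 0.0949).

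Immediate-early genes, which respond within minutes to stimulation, were lower in libraries labelled Gata2cKO and varied widely between libraries. Of 19 tested members of the list of immediate-early and stress genes 3 fell and 2 rose (7 and 2 adjusted over the list alone), with camera adjusted p = 0.00103 (adjusted p = 0.729 with an estimated correlation). Without control replicate 1, 12 fell and 2 rose, and in the other removals 0 to 3 fell and 0 or 1 rose. Fosb was at 23.2, 72.5 and 46.2 TPM in controls and 1.204, 1.84 and 6.55 TPM in Gata2cKO, and Fos at 104, 247 and 190 TPM in controls and 10.2, 16.9 and 65.9 TPM in Gata2cKO. Their log2 fold changes were -3.60 (SE 0.52, limma adjusted p = 0.0128) and -2.84 (SE 0.62, limma adjusted p = 0.0374). Ier2, named after its values were seen, was the third that fell. The members that rose were the heat-shock genes Hspa1a, from 8.88 ± 2.16 to 16.02 ± 0.775 TPM, and Hspa1b, from 25.8 ± 3.44 to 45.7 ± 9.16 TPM (SD, n = 3 each), a near-identical pair that shares reads, so the value of each is uncertain. All 4 lost their calls when a library was left out (Fosb adjusted p = 0.0532 without Gata2cKO replicate 2, Fos 0.114 without Gata2cKO replicate 1, Hspa1a and Hspa1b 0.0968 and 0.111 without Gata2cKO replicate 3).

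Replication histone genes were among the genes with the lowest log2 fold changes. Hist1h3g was at 95.3, 17.3 and 21.4 TPM in controls and 4.88, 5.87 and 3.68 TPM in Gata2cKO. Hist1h1d, Hist1h2bl and Hist1h2bj fell by 2.23, 1.84 and 1.57 on the log2 scale (limma adjusted p = 0.0235, 0.0477 and 0.00847). Control replicate 1 had the highest value of each of these in controls and also the highest mitochondrial share. Hist1h2bj kept its call in each removal of a library, whereas Hist1h3g, Hist1h1d and Hist1h2bl lost theirs (highest adjusted p 0.126, without Gata2cKO replicate 3, 0.0903, without Gata2cKO replicate 1, and 0.144, without Gata2cKO replicate 3). Most such transcripts lack a poly-A tail and the genes are near-identical copies, so poly-A libraries measure them poorly and the value of each is uncertain.

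Of 40 tested proliferation genes 0 passed in either direction by limma, also adjusted over the list alone, 11 had an unadjusted p under 0.05, and the authors' deposited table calls 7. Leaving out control replicate 1 gave 2 that rose and 1 that fell, and the other removals gave 0. Cenpa, a centromeric histone gene, had the smallest p (125 ± 0.717 and 99.9 ± 9.90 TPM, limma adjusted p = 0.0686), and the list did not pass (camera adjusted p = 0.674). Of 19 genes of p53 signalling and apoptosis 2 rose, Perp and Ccng1, also adjusted over the list alone (camera adjusted p = 0.982). Both lost their calls without Gata2cKO replicate 1 (adjusted p = 0.0657 and 0.148). Of 17 hypoxia and glycolysis genes 2 rose, Egln3 and Tpi1, also adjusted over the list alone (camera adjusted p = 0.169; 0.0427 without Gata2cKO replicate 2). Both lost their calls without Gata2cKO replicate 1 (adjusted p = 0.0631 and 0.189). By limma 0 members passed, also adjusted over the list alone, among 9 interferon genes, 8 adipocyte genes and 9 genes of Müllerian duct development (camera adjusted p = 0.769, 0.572 and 0.817). They had 1, 2 and 1 members at an unadjusted p under 0.05, and the authors' deposited table calls 0, 0 and 1. Their smallest p belonged to Rsad2, Lpl and Emx2 (limma adjusted p = 0.179, 0.107 and 0.0795). The proliferation, apoptosis and interferon lists had a median log2 fold change above 0 and a downward direction in camera, and the Müllerian list a median below 0 and a mean above it. The Sertoli and germ cell markers passed camera downward (adjusted p = 0.0339; adjusted p = 0.593 with an estimated correlation), although 0 of 8 tested members passed by limma, also adjusted over the list alone. At an unadjusted p under 0.05 there were 3, and the authors' deposited table calls 0. Aard had the smallest p (19.3 ± 2.64 and 14.3 ± 1.79 TPM, limma adjusted p = 0.0889) and Sox9 was the most abundant (30.8 ± 4.44 and 26.5 ± 4.36 TPM). That call was lost without control replicate 1 (adjusted p = 0.102) and without Gata2cKO replicate 1 (adjusted p = 0.0563). Among lists too small to test, 0 of 4 skeletal muscle genes and 0 of 4 sex chromosome genes passed limma, 0 at an unadjusted p under 0.05 and 0 in the authors' deposited table, with Tnni2 at 8.92 ± 2.46 and 7.07 ± 1.74 TPM and the Y-linked gene Ddx3y at 28.5 ± 1.97 and 31.4 ± 0.498 TPM (SD, n = 3 each).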

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

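Of the tests in this part, the 3 other scalings of the TPM, the filter at a TPM of 5, the library weights, the GC correction and the authors' test were chosen after the data were seen. The 919 changed genes became 1906 in the authors' deposited test (945 lower), 76 with a log2 fold change of at least 1 in size, 4751 with a weight per library (3080 higher, 1671 lower) and 1479 with the GC trend removed (1119 higher, 360 lower; 892 of the 919 kept). Median-of-ratios scaling gave 397 lower genes, upper-quartile scaling 342, and a total without mitochondrial genes 432 higher genes. Leaving out 1 library gave 116 to 1539 changed genes (87 to 1108 higher, 29 to 431 lower), lowest without Gata2cKO replicate 1 and highest without control replicate 1, and for genes of the lists 27 to 138 calls in place of 99. The cause was not tested, except that 5 libraries hold less information than 6. Pseudocounts of 0.1 and 5 gave 910 and 913 genes, no filter 877 and the higher filter 784, within 1.5 times of 919.

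The replicate numbers did not pair the samples. Correlations of the deviations of same-numbered samples were 0.25, -0.07 and 0.04, and 1 of 3 control samples correlated best with its own number. With the replicate block 774 genes were called, 633 of them among the 919, with 10 lists past the test.

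The Gata2 log2 fold change was 0.019 with the GC trend removed and ranged from -0.14 to 0.11 over the removals of 1 library, and no setting put it past the threshold. Hba-a1 ranged from -0.17 to 0.49 over those removals. The cause was not tested. No other named gene changed sign. Of the 103 named genes other than Gata2, 92 kept their direction and side of the threshold with median-of-ratios scaling, 92 without a filter, 94 with the replicate block and 50 to 100 over the removals of 1 library. The 10 shifted lists became 0 of 30 with an estimated correlation (smallest p 0.0616, smallest adjusted p 0.593, 0 at an unadjusted p under 0.05), and 11 lists had an unadjusted p under 0.05 in camera. The estimates for those 10 lists ran from 0.02 (Sertoli and germ cell) to 0.75 (immediate-early and stress). All lay above the preset of 0.01, so the list shifts depend on that preset. Directional fry asks whether a list shifted in 1 direction, without other genes for comparison, and so is no check on camera. It called 8 lists, 6 of them among the 10. The others were the androgen list and the FGF and RET list (directional fry adjusted p = 0.0174 and 0.0494). It did not call the epithelial, smooth muscle, Sertoli and germ cell or immediate-early lists. In mixed fry the epithelial, smooth muscle and immediate-early lists passed (adjusted p = 0.00108, 0.000127 and 0.0174). The Sertoli and germ cell list did not (mixed fry adjusted p = 0.226). The other settings gave 7 to 12 lists in camera. The Sertoli and germ cell list lost its call with median-of-ratios scaling (adjusted p = 0.0800) and with the GC trend removed (adjusted p = 0.0716), among others, and the smooth muscle list without a filter (adjusted p = 0.0675) and with library weights (adjusted p = 0.0650). The neural list passed without mitochondrial genes in the total (adjusted p = 0.0428) and the interferon list, downward, with library weights (adjusted p = 0.0339). The planned edgeR, voom and DESeq2 fits and count filters were not run because they need counts, and without read depth the counting error of low genes stays unknown.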

Other observations

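Of the tests in this part, those of the GC trend and of the region around Gata2 were set before their results were seen. The other tests were chosen after.

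The count of changed genes did not rest on control replicate 1, the library with the highest mitochondrial share. Of the 919 genes 877 were also called without it, and 892 after each library's GC trend was removed, which argues against either as the whole cause. Removal of control replicate 1 raised the count to 1539, so calls were easily kept there, whereas each other removal kept only 114 to 257 of the 919. The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 919 genes and the highest other split 0, so the real split itself was the only 1 of the 10 to give that many. The genotype in the labels stays open as a biological explanation, untested against handling or litter because these are not recorded.

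Replication histone genes were highest in control replicate 1, the library that stood apart, whereas Fos and Fosb were lowest among controls there. Without control replicate 1 the median log2 fold change of 32 histone genes was still -0.45 (SE of the mean score 0.19; -0.85 with all libraries). With 7 that fell and 1 that rose there, that library does not account for all of the calls. The summed histone level nearly met between the groups without it, at 1439 TPM in control replicate 3 and 1394 TPM in Gata2cKO replicate 3. For the immediate-early genes a candidate explanation is that the time or handling before freezing differed between the groups. Of the 16 members other than heat-shock genes 15 had a negative log2 fold change (score difference -0.99, SE 0.40), whereas the heat-shock gene Hspa1a rose (log2 fold change 0.81, SE 0.16). A rise of Hspa1a was set down as counting against handling, but that bound was too strict, since Fos and heat-shock genes answer to different stimuli and Hspa1a shares reads with Hspa1b, so handling and genotype cannot be told apart here.

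The lists of epithelial, mesothelial, endothelial, tubule and mast cell markers were shifted upward by camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.593 each). By limma 6 of 23, 4 of 10, 4 of 17, 4 of 6 and 3 of 6 members rose. Mesenchymal genes moved both ways: Tcf21, Nr2f1 and Osr2 fell, Foxf1, Lox and Mfap5 rose, and the list as a whole was not shifted. A lower share of mesenchyme in the libraries labelled Gata2cKO would raise the markers of all other cell types alike. Mast cell scores rose more than epithelial scores by 0.68 (log2, SE 0.12), which argues against a lower share as the whole cause for the mast cell markers. More mast cells in the tissue may still account for the members that rose, at levels of 169 ± 5.10 TPM for Tpsb2 and 81.6 ± 5.27 TPM for Cma1. Adjusted over the list alone, 5 of the 6 tested mast cell markers rose and 1 fell. Mesothelial scores rose more than macrophage scores, whose list did not pass camera, by 0.26 (SE 0.034), and tubule scores more than epithelial scores by 0.23 (SE 0.063). These gaps are the largest in standard errors among the 15 pairs of the epithelial, mesothelial, endothelial, tubule, macrophage and neural scores, with no allowance for the number of pairs. Tubule minus macrophage (0.29, SE 0.14) was the only other past 2 standard errors, and mesothelium differed less from epithelium (0.20, SE 0.19) and endothelium (0.16, SE 0.086). A lower share alone would open no such gap if each marker belonged to 1 cell type and the scale treated all levels alike. Neither holds in full: Krt19 is in both the epithelial and the mesothelial list, and log2(TPM + 1) understates the change of genes with low values. The pairs were picked after the data were seen, and a gap does not show which side of a pair made it. For the mesothelial and tubule markers no conclusion is therefore drawn from these gaps. A lower share, more mesothelium or tubules in the dissected tissue, or a change within these cells, stays open. For the epithelial and endothelial markers the largest gap over another type among these 15 pairs, endothelium minus macrophage, was 0.10 (SE 0.057). It lies within 2 standard errors. The Sertoli and germ cell score, outside these pairs, went down (-0.26, SE 0.11), which a lower share of mesenchyme alone would not produce. Of its 8 tested members 0 passed by limma, so no conclusion is drawn from it. For the epithelial and endothelial markers a lower share and a change within these cells cannot be told apart.

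Sequence carried along with a floxed allele from another strain could change genes near Gata2. Controls also carried 1 floxed allele, so such sequence would differ only in its number of copies, which makes its effect harder to see here. Of 152 other tested genes within 20 Mb of Gata2 on chromosome 6, 10 were called (6.58%), against 909 of 12136 elsewhere (7.49%; one-sided Fisher's exact p = 0.709, odds ratio 0.87 with a 95% interval of 0.407 to 1.65). The interval leaves a modest excess open, and with 10 of 919 genes in this region the flanking sequence itself does not account for the count.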
